A study of Mus musculus with 12 samples.

How the data were processed

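The data are 10x Genomics single-cell 3' v3 libraries with CITE-seq and cell hashing (TotalSeq-A antibodies), per the labels' protocols. Brains of perfused female C57BL/6 mice were digested and enriched for immune cells by percoll gradient centrifugation, per the labels' protocols. Each brain was stained with a pool of 31 antibodies and its own hashing antibody, and 6 brains of a day, vehicle and ABX together, were loaded into 1 well, per the study design. The 12 GEO samples are the RNA, antibody and hashtag libraries of 4 wells (days 0, 4, 8 and 14). The deposited values are whole UMI counts per gene, antibody or hashtag and cell barcode, not normalized, in matrices already limited to cell barcodes. They were made with Cell Ranger 7.2.0, per the file headers. Cell Ranger 7.2, Seurat 5 and the build mm10 are named, with no role given, per the submitters' processing notes. The gene annotation and the antibody counting settings are not given in the sources used here.

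The files held 31062 genes, 42 antibody entries and 14 hashtag entries; the 31 antibodies of the panel and 6 hashtags were used. Genes sharing 1 of 71 symbols were kept apart by identifier. No source used here ties a hashtag to vehicle or ABX, so each comparison of ABX with vehicle, its interaction with day, its class shares and its surface proteins, planned before the data were examined, was left out. As planned for that case, all mice of a day were its replicates, so a change between days is an average over an unstated mix of treatments. Each day was 1 well, so day and well cannot be told apart. Hashtag numbers are names of mice within a well and pair nothing across wells.

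Barcodes with at least 300 genes, 500 UMIs and at most 10% mitochondrial UMIs were kept (16401, 7017, 14093 and 16288 of 17221, 7328, 14514 and 17327 at days 0, 4, 8 and 14). Hashtags were assigned with HTODemux of Seurat 5.3.0 (positive quantile 0.99), which gave 11108, 5542, 9410 and 11934 cells with 1 hashtag, 1928, 808, 1938 and 1385 with several, and 3365, 667, 2745 and 2969 with none. MULTIseqDemux gave the same call for 92.3%, 97.2%, 92.2% and 98.1% of the cells to which HTODemux gave 1 hashtag. Cells with several hashtags were removed as doublets; doublets within a mouse remain. The automatic Scrublet threshold (scanpy 1.11.5) called 2.20%, 0.0285%, 22.5% and 4.94% and was judged to have failed at day 4, so in the alternative that removes them doublets were called by rank, at 13.0%, 5.20%, 11.2% and 13.0%. Cells were clustered on 2000 variable genes, 30 principal components and 20 neighbours with leidenalg 0.10.2 (python-igraph 0.11.9, resolution 1.5, seed 1) into 43 clusters. A cluster was named X-like from markers fixed before the data were examined, where at least 3 were detected and its leading genes did not go against the name; 11 clusters stayed unnamed, and among them those led by Rhox5, Spp1 and Elane were compared by number of cells. The genes that describe these clusters were taken from their leading genes after the data were seen. Unnamed cluster 6, of low UMI counts, held 695, 196, 441 and 221 cells and was put with the microglia in an alternative.

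Shares were compared by a two-sided exact permutation test of the difference of means over all 924 arrangements of 6 against 6 mice (SciPy 1.17.1), with Benjamini-Hochberg adjustment over 57 tests; a planned stratum for treatment could not be used. All mice had over 100 cells. Counts were summed per mouse and class for mice with at least 20 cells of the class and tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, 1 fit over days, Benjamini-Hochberg threshold 0.05); adjusted p values of genes and antibodies are from this tool. Microglia sums per mouse ranged from 1682700 to 19161000 UMIs. Standard errors are the absolute log2 fold change over the square root of F. Comparisons of 8 further classes at day 14 were added after the data were seen, giving 11 gene comparisons in 9 classes. The B cell comparison was run, set aside under a minimum of 5 mice chosen afterwards, and is reported after all. Antibody counts were summed and tested in the same way.

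Gene lists fixed before the data were examined were homeostatic microglia, disease-associated microglia, interferon response, MHC class II, MHC class I presentation, inflammatory cytokines and NF-kB, cell cycle, immediate early and dissociation, complement, glycolysis, oxidative phosphorylation, cholesterol synthesis, aryl hydrocarbon receptor targets, phagocytosis and lysosome, cytotoxic, checkpoint and exhaustion, naive and memory T cell, and markers of lymphocytes, neurons and glia, neutrophils and red cells. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, beside an estimated correlation and fry. The genes named in microglia follow a rule set before the data were examined. Among genes past 0.05 with a mean log2 CPM of at least 5, it takes the 6 largest rises and 6 largest falls at day 14, the 3 largest of each at days 4 and 8, and up to 3 members of each list with the smallest p. Genes of ribosomal proteins, mitochondria, hemoglobin, Xist and the Y chromosome are left out of the largest changes, the 6 antibodies with the smallest p are named, and where no gene passes the 5 with the smallest p are named as not passing. Some results of single genes are not reported here. In added classes 3 rises, 3 falls and members of the 4 lists with the smallest camera p were named. Hist1h, hemoglobin and Ifit3 genes have near-identical copies and are uncertain.

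RNA of other cells in a class was estimated from markers that the class should lack, as a percent of its counts. This percent is the level of the markers in the class over their level in all barcodes of the well. It states how much RNA of the whole well the markers would need, and can rise while they fall if the well holds less of them. A gene was counted as one that such RNA could supply at 50% or more of its level. These markers were revised after estimates were seen: Gpr34 and Fcrls were dropped from the microglial set, and that set was not used for myeloid classes. Alternatives were DESeq2 1.42.0, no low-count filter, MULTIseqDemux, a stricter cell filter (800 genes, 1500 UMIs, 5% mitochondrial), removal of Scrublet-called doublets, other denominators of shares, edgeR on cell numbers, other scalings of antibodies, and each mouse left out. Added after the data were seen were leaving out genes that RNA of other cells could supply, cluster 6 with the microglia, and shares of immune cells. The change relative to T cells of the same mice, a different quantity, was tested as well after the data were seen, for genes and antibodies. Chance was checked with 100 drawn splits of the mice per comparison (84 for B cells).

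The gene test was tested on simulated data drawn from the real means and library sizes. For microglia it recovered 50 of 50 genes at 4-fold, 42 of 50 at 2-fold, 34 of 50 at 1.5-fold and 43 of 49 at 0.5-fold, with 3 false calls among 12425 genes. For monocytes it recovered 50 of 50, 39 of 50, 21 of 48 and 34 of 49, with 9 false calls among 8569. In that draw camera gave a list with no simulated change a p of 0.00692, so its calls in monocytes can include false ones. At 2-fold it recovered 43 of 49 genes in T cells, 42 of 50 in NK cells, 31 of 50 in neutrophils, 44 of 50 in cDC2, 38 of 50 in border-associated macrophages and 36 of 50 in endothelial cells. The antibody test recovered 6 of 6 changes with 0 false calls among 25. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.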

Results

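Immune cells of the brain were profiled by CITE-seq, which counts RNA and surface-bound antibody tags in the same droplets, in 24 female C57BL/6 mice. Brains came from naive mice (day 0) or were collected 4, 8 and 14 days after an injection into the carotid artery, and the study design describes the latter as bearing metastases. Mice had received vehicle or ABX, an abbreviation that the labels do not spell out. Each of 6 brains per day was stained with its own hashtag and with 31 antibodies, and the brains of a day, vehicle and ABX together, were pooled into 1 well. No source used here ties a hashtag to a treatment, so the effect of ABX was not analysed here and the 6 mice of a day were taken as its replicates. Day and well cannot be told apart, and the number of ABX mice per day is not stated. The wells of days 0, 4, 8 and 14 held 17221, 7328, 14514 and 17327 barcodes with 198860306, 104694044, 239269765 and 492236783 RNA UMIs. After filters, 37994 cells with exactly 1 hashtag remained, 463 to 3219 per mouse, with a median per mouse of 8220 to 13684 RNA UMIs per cell. Before filters the median per well was 9162 to 11970 RNA UMIs per barcode. Median antibody UMIs per barcode, also before filters, were 321 at day 0 against 3375, 2250 and 3565 at days 4, 8 and 14.

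To determine how the cell makeup of the suspension changed with time, the share of each cell class among the kept cells of a mouse was compared with day 0. Microglia-like cells, the resident macrophages of the brain, made up 53.9 ± 4.62% of cells at day 0 (SD, n = 6 mice) and 13.9 ± 6.18% at day 14 (exact permutation test, adjusted p = 0.0112). Their shares of 65.5 ± 11.6% at day 4 and 59.2 ± 7.04% at day 8 did not pass (adjusted p = 0.106 and 0.254). T cell-like cells rose from 3.78 ± 1.01% to 7.35 ± 2.81%, 8.13 ± 4.11% and 10.999 ± 4.05% at days 4, 8 and 14 (exact permutation test, adjusted p = 0.0137, 0.0112 and 0.0112). Monocyte-like cells rose from 2.30 ± 0.582% to 4.21 ± 1.27% at day 8 and 11.7 ± 4.77% at day 14 (adjusted p = 0.0137 and 0.0215), with 2.36 ± 1.09% at day 4. Among dendritic cells, cDC2-like cells rose from 2.21 ± 0.570% to 5.85 ± 2.00% at day 14 (adjusted p = 0.0137). Migratory dendritic cell-like cells, marked by the lymph node homing receptor Ccr7, rose from 0.128 ± 0.0919% to 2.09 ± 0.750% (adjusted p = 0.0112).

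Border-associated macrophage-like cells, which line the meninges and vessels, fell from 4.13 ± 0.448% at day 0 to 0.923 ± 0.422%, 1.59 ± 0.636% and 2.16 ± 0.690% at days 4, 8 and 14 (exact permutation test, adjusted p = 0.0112 each). B cell-like cells fell from 4.73 ± 4.29% to 0.971 ± 0.631% at day 8 and 1.56 ± 0.762% at day 14 (exact permutation test, adjusted p = 0.0137 and 0.0215), with 2.00 ± 1.42% at day 4 (adjusted p = 0.193). This class joins cluster 20, led by Cd79a and Ms4a1, and cluster 22, with Vpreb3 and Vpreb1 among its leading genes. They held 331 and 313 cells at day 0. Endothelial-like cells fell from 4.50 ± 2.00% to 1.17 ± 0.418% and 0.975 ± 0.324% at days 4 and 8 (adjusted p = 0.0137 and 0.0112) and stood at 5.82 ± 2.56% at day 14 (adjusted p = 0.478). Fibroblast-like cells fell from 1.77 ± 0.736% to 0.393 ± 0.256% and 0.549 ± 0.323% at those days, and mural cell-like cells from 0.936 ± 0.579% to 0.0624 ± 0.0804% and 0.185 ± 0.123%. NK cell-like cells, at 2.78 ± 0.724% on day 0 and 5.21 ± 2.38% on day 14, did not pass (adjusted p = 0.0914). Neutrophil-like cells, at 3.56 ± 3.38% and 3.83 ± 2.39%, did not pass at any day.

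Clusters that had too few fixed markers for a name were compared by their leading genes. A cluster led by Ms4a7, Spp1, Gpnmb and Fabp5 rose from 0.0629 ± 0.130% of cells to 1.68 ± 0.906% at day 8 and 6.09 ± 2.27% at day 14 (exact permutation test, adjusted p = 0.0112 each). A pair of clusters led by Rhox5, Wfdc2, Cdh13 and Krt8, a keratin of epithelial cells, held 0 of 11108 cells at day 0, which allows a share of up to 0.0270%. They held 0 of 5542 cells at day 4, 0.414 ± 0.349% at day 8 (adjusted p = 0.0360) and 17.9 ± 9.88% at day 14 (adjusted p = 0.0112), where single mice ranged from 2.10% to 33.02%. Their median UMI counts, 124525 and 96982, were 11.7 and 9.14 times those of their wells, and the clusters also held 42 and 5 cells at day 8. With the range among mice of the day 14 well, these values argue against 1 effect on all cells of that well as their source. With 1 well per day, a change of their share with day still cannot be told apart from a difference between wells. A cluster led by the neutrophil precursor genes Prtn3, Elane and Mpo fell from 2.43 ± 1.15% to 0.773 ± 0.498% at day 14 (adjusted p = 0.0215).

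In all, 24 of 57 tests over 19 classes passed, and with 924 arrangements of 6 against 6 mice the smallest two-sided p before adjustment is 0.00216. Shares describe the percoll suspension, not the brain, and a rise in 1 class lowers the share of all others. Among immune cells alone, NK cell-like cells rose at day 14 (7.16% against 3.11%, exact permutation test, adjusted p = 0.0281). There the fall of B cell-like cells at day 14 no longer passed (-2.95 rather than -3.17 points, exact permutation test, adjusted p = 0.0844). As a share of cells other than microglia, the rises of T cell-like and cDC2-like cells at day 14 and the fall of endothelial-like cells at day 4 no longer passed. The differences were 3.48, 1.15 and -7.66 points there, against 7.22, 3.63 and -3.33 as shares of all kept cells. The stricter cell filter took the differences of mural cell-like cells from -0.873 to -0.0455 percentage points at day 4 and from -0.751 to -0.0238 at day 8 and that of the Elane cluster from -1.65 to -1.23, ending each call. In edgeR on cell numbers the call of monocyte-like cells at day 8 was lost, at a log2 fold change of 0.875. Without day 4 mouse 1 the rise of microglia-like cells at day 4 passed, at 15.8 rather than 11.6 points. NK cell-like cells at day 14 passed without day 14 mouse 1 (3.14 rather than 2.43 points) and in edgeR on cell numbers (log2 fold change 0.91). Calls were also gained by B cell-like cells at day 4 (without day 4 mouse 1, at -3.28 rather than -2.73 points, and in edgeR on cell numbers), NK cell-like cells at day 8 (without day 8 mouse 5, at 2.47 rather than 1.97) and migratory dendritic cell-like cells at day 8 (without day 8 mouse 6, at 0.407 rather than 0.317, and with Scrublet-called doublets removed). Choroid plexus-like cells at day 8 gained one under MULTIseqDemux assignment (0.288 rather than 0.162). Leaving out single mice ended the calls of B cell-like cells at day 14 (day 14 mouse 1, 2, 3, 5 or 6), mural cell-like cells at day 8 (day 8 mouse 3, 4, 5 or 6) and the Rhox5 clusters at day 8 (any 1 day 0 mouse). The differences then stood at -2.97 to -3.23, -0.723 to -0.751 and 0.414 percentage points, against -3.17, -0.751 and 0.414 with all mice, with fewer arrangements of the mice. The call of the Rhox5 clusters at day 8 was also lost under MULTIseqDemux assignment, where the difference was 0.325 rather than 0.414 points. Day 0 mouse 6 held 13.4% B cell-like cells; without it the difference of this class from day 0 was -1.45 rather than -3.17 percentage points at day 14 and -2.04 rather than -3.76 at day 8. Without day 8 mouse 2 the difference of T cell-like cells at day 8 was 2.79 rather than 4.35 points.

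**Figure D1:**
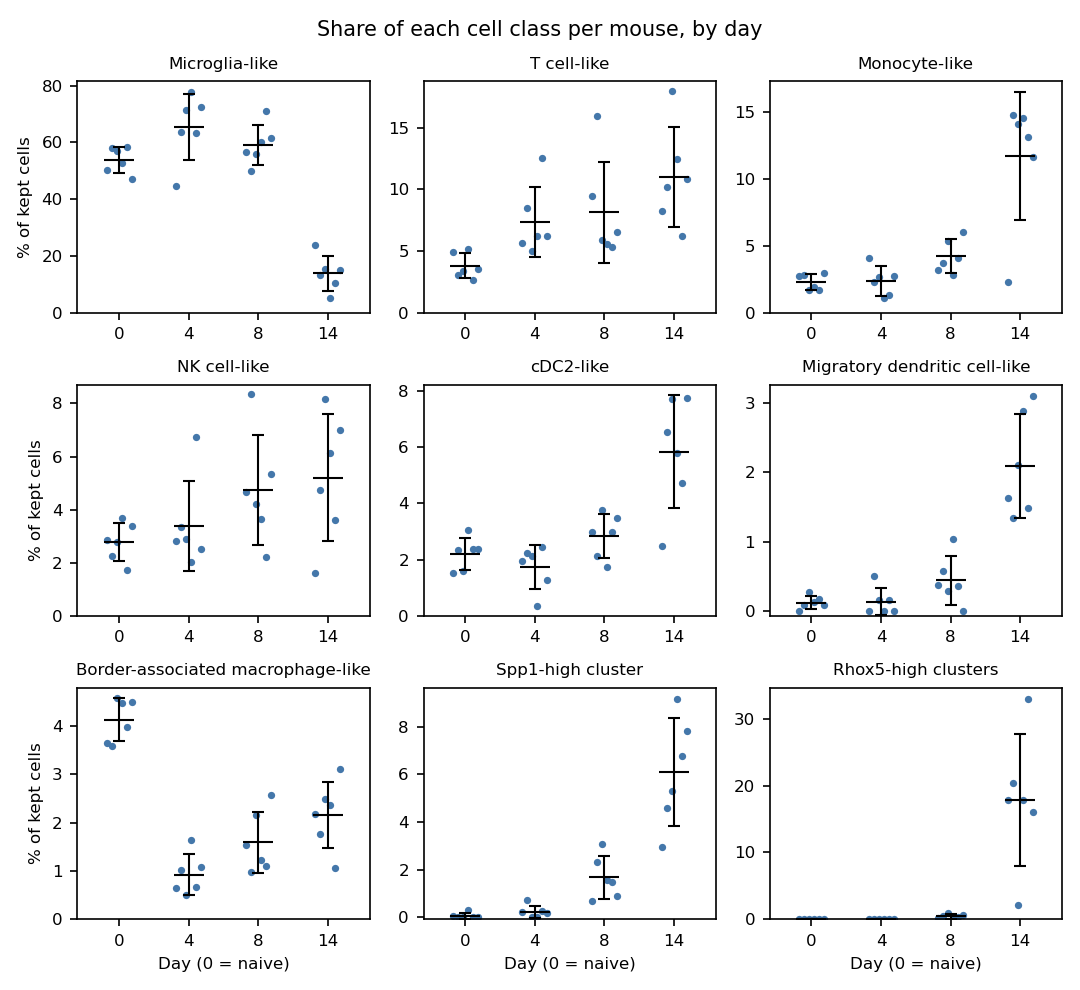
Share of each of 9 cell classes (percent of a mouse's kept cells, y axis) by day after injection (x axis); each dot is 1 mouse, 6 per day, the bar is their mean and the error bar their SD. Microglia-like cells fell from a mean of 53.9% at day 0 to 13.9% at day 14, while the Rhox5 clusters reached 17.9%.

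To determine what changed in microglia early after injection, their RNA counts summed per mouse were compared between day 4 and day 0. Genes of the homeostatic microglia list, which mark resting microglia, rose. Of 12 tested, 7 passed upward and 0 downward (8 and 0 adjusted over the list alone). Among them were the fractalkine receptor Cx3cr1 (log2 fold change 0.70 ± 0.06 SE, edgeR adjusted p = 7.8e-11), Sall1 (0.47) and Siglech (0.40). Inflammatory cytokine and NF-kB genes fell, 8 of 17 passing downward and 2 upward (10 and 2 adjusted over the list alone). The cytokine Il1b fell from 129 ± 31.2 to 43.1 ± 11.2 CPM (normalised UMI counts, SD, n = 6 mice a day; log2 fold change -1.59 ± 0.27, edgeR adjusted p = 2.33e-05), and the NF-kB inhibitors Nfkbia and Tnfaip3 changed at -0.47 and -0.52 on the log2 scale. MHC class II genes, which present antigen to helper T cells, fell in 5 of 6 tested, H2-Eb1 with a log2 fold change of -2.30 ± 0.43. RNA of other cells could supply 100% of the day 4 level of H2-Eb1. Oxidative phosphorylation genes rose in 7 of 13, among them Cox6c (0.59) and Cox7c (0.57). In T cells of the same mice Cox6c and Cox7c rose by 0.75 and 0.87, and neither was shown to rise more in microglia.

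Camera called these 4 lists at day 4, with medians of 0.34, -0.45, -1.16 and 0.36 on the log2 scale (adjusted p = 0.00766, 0.0183, 0.0136 and 0.0136, each adjusted p = 0.742 with an estimated correlation). Immediate early and dissociation genes, induced within minutes by stress, passed downward in 9 of 16 and upward in 3, with Atf3 at -0.74 and Klf6 at -0.70. Their median was -0.16 but their mean 0.02, and camera did not call them (adjusted p = 0.104). Of 19 interferon response genes 3 rose and 1 fell (camera adjusted p = 0.511), with Xaf1 at 0.67 and Stat2 at -0.89. Glycolysis genes passed upward in 1 and downward in 5 of 10, where the hexokinase Hk2 rose (0.57) and Pkm fell (-0.40). For the lists not called, genes up and down of those tested were 1 and 1 of 15 for cell cycle, 1 and 3 of 15 for disease-associated microglia, 2 and 1 of 11 for MHC class I. They were 0 and 1 of 11 for cholesterol synthesis, 0 and 1 of 6 for complement and 0 and 2 of 12 for phagocytosis. Counts were 0 and 2 of 7 for checkpoint genes, 2 and 0 of 3 for cytotoxic genes and 1 and 2 of 4 for naive and memory T cell genes. Adjusted over the list alone these counts were equal except disease-associated microglia, at 0 up and 3 down.

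Over all 12560 genes tested, 2735 rose and 2621 fell at day 4 (edgeR, 6 against 6 mice), of which 405 and 175 changed at least 2-fold. The largest rises were AY036118 (3.04 ± 0.08, edgeR adjusted p = 7.79e-23; 301 ± 15.3 against 36.7 ± 2.08 CPM), Gm26778 (2.43) and Gm44511 (2.28), and the largest falls Itga5 (-1.63), Il1b and the transcription factor Batf (-1.58). AY036118 and Gm44511 rose in T cells of the same mice too, by 3.498 and 2.39. Markers of other cells moved as well: neutrophil genes fell in 3 of 6, red cell genes in 1 of 5 and neuron and glia genes in 2 of 6 with 1 rising. Lymphocyte genes rose in 2 of 3. Microglia clusters 2, 1 and 0 held most of the class at day 0 and clusters 0, 4 and 1 at day 4. The genes named for day 4 lay beyond all day 0 mice in 6 of 6 mice. The difference between microglia and T cells of the same mice passed for 299 genes. It passed in the called direction for 2 of 53 genes named by the rule for day 4, and against it for 1.

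To determine what changed in microglia at the intermediate time, day 8 was compared with day 0. Spp1, the secreted protein osteopontin, rose by 2.59 ± 0.75 (edgeR adjusted p = 0.00676). Up to 54.3% of the Spp1 level could be RNA of other cells, and its call was lost when Scrublet-called doublets were removed, where its log2 fold change was 1.84. The lipoprotein lipase gene Lpl rose by 0.90 ± 0.24 (edgeR adjusted p = 0.00338) and the lipid carrier Fabp5 by 1.24. Of 15 disease-associated microglia genes 4 passed upward and 0 downward, without a call of the list (camera adjusted p = 0.770). Homeostatic genes passed upward in 6 and downward in 3 of 12 (7 and 3 adjusted over the list alone; camera adjusted p = 0.218), with Cx3cr1 at 0.44, Gpr34 at 0.36 and Sall1 at 0.28. Oxidative phosphorylation genes rose in 8 of 13 (median 0.19, camera adjusted p = 0.00455, camera adjusted p = 0.670 with an estimated correlation), for example Ndufa4 (0.42) and Cox7c (0.34). In T cells of the same mice Ndufa4 and Cox7c rose by 0.56 and 0.59, and neither was shown to rise more in microglia. Immediate early genes fell in 7 and rose in 3 of 16 (median -0.11; camera adjusted p = 0.0434; adjusted p = 0.670 with an estimated correlation), Ier2 at -0.83 and Jund at -0.59.

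Inflammatory genes passed downward in 6 and upward in 0 of 17 at day 8 (camera adjusted p = 0.0891), with Il1b at -1.59 ± 0.26 (edgeR adjusted p = 2.36e-05). MHC class II genes passed downward in 5 of 6 (camera adjusted p = 0.0697), H2-Eb1 at -1.19 (100% possible from other cells). Cell cycle genes passed upward in 5 of 15 (3 adjusted over the list alone), with Birc5 at 0.98, of which RNA of other cells could supply 100%. Cholesterol synthesis genes passed upward in 3 of 11, with Sqle at 0.93 (51.1% possible from other cells, 19.6% at day 0) and Idi1 at 0.73 (34.8% and 8.19%). Of 19 interferon genes 1 passed upward (0 adjusted over the list alone) and 1 downward, Stat2 (-0.81). Glycolysis genes passed upward in 1 and downward in 2 of 10, MHC class I genes in 1 and 2 of 11 (1 and 1 adjusted over the list alone). Phagocytosis genes passed in 0 and 3 of 12 and checkpoint genes in 0 and 2 of 7. Complement genes passed in 0 and 0 of 6, cytotoxic genes in 1 and 0 of 3 (2 and 0 adjusted over the list alone) and naive and memory T cell genes in 1 and 2 of 4.

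The largest rises at day 8 were S100a6 (2.79 ± 0.10, edgeR adjusted p = 9.86e-19), a level that RNA of other cells could supply in full, AY036118 (2.79) and Gm26778 (1.83). The kinase Pim1 (-1.61 ± 0.14, edgeR adjusted p = 8.75e-10) and Itga5 (-1.41) fell most beside Il1b. Neutrophil markers fell in 6 of 6 (median -1.53; camera adjusted p = 3.96e-10; adjusted p = 0.000198 with an estimated correlation). Red cell markers fell in 5 of 5 (median -1.89; camera adjusted p = 0.0264; adjusted p = 0.670 with an estimated correlation). Lymphocyte markers passed upward in 1 of 3 (2 adjusted over the list alone), and neuron and glia markers in 1 upward and 1 downward of 6, where the median was -0.13 and the mean 0.08. Other counts adjusted over the list alone equalled those over all genes. Over all 12560 genes, 2527 rose and 2555 fell (edgeR, 6 against 6 mice), 316 and 127 of them at least 2-fold, and 229 genes changed differently in microglia and in T cells of the same mice. Clusters 0, 1 and 4 held most microglia at day 8. Fabp5 lay beyond all day 0 mice in 3 of 6 mice, and H2-Eb1, Birc5, Sqle and Idi1 in 5, while the other genes named for day 8 did so in 6. Without day 8 mouse 5 the log2 fold change of H2-Eb1 was -1.85.

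To determine how microglia of brains with late metastases differ from naive microglia, day 14 was compared with day 0. Interferon response genes, which restrict viruses and mark interferon signalling, rose in 19 of 19 tested (19 adjusted over the list alone; median log2 fold change 2.46). Isg15 rose from 11.3 ± 2.30 to 126 ± 131 CPM (SD, n = 6 mice a day; log2 fold change 3.49 ± 0.41 SE, edgeR adjusted p = 1.66e-07), the nucleic acid sensor Zbp1 by 3.54 ± 0.39 (edgeR adjusted p = 6.7e-08) and Ifitm3 (ENSMUSG00000025492) by 3.29 ± 0.39. For these genes a separate estimate summed the RNA of 14 other classes, each in the amount its markers reach in microglia. Such RNA could supply a median of 28.7% of their day 14 level and 68.9% of that of Ifitm3. The estimate behind the percents given for other genes was lower for each of these 19 genes. It put Ifitm3 at 18.9% and Irf7 at 10.3%, where the separate estimate put Irf7 at 75.6%, so these percents are not comparable. The separate estimate was not made for other genes. A low percent, or none, thus does not show that the RNA of a gene is from the class itself. Genes of disease-associated microglia, a state linked to lipid handling and phagocytosis, rose in 11 of 15 (12 adjusted over the list alone; median 1.80). Among them Spp1 rose by 5.75 ± 0.66 (96.0 ± 107 against 1.83 ± 0.600 CPM, edgeR adjusted p = 1.28e-07) and Lpl by 2.48 ± 0.25 (edgeR adjusted p = 1.73e-08). Neither was shown to rise more than in T cells of the same mice (differences 2.38 and -1.04, edgeR adjusted p = 0.372 and 0.827). Both were too low in T cells to be tested in that class alone. The 10 leading genes of the cluster led by Ms4a7 and Spp1 stood in microglia at a median of 1.93% of their level in that cluster. RNA of that cluster could thus contribute to Spp1. Homeostatic genes fell in 10 of 12 (10 down and 1 up adjusted over the list alone; median -0.33), Gpr34 at -0.71 ± 0.10 (edgeR adjusted p = 1.42e-06), Cx3cr1 at -0.41 and Sall1 at -0.46.

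Inflammatory genes rose in 14 of 17 at day 14 (14 up and 1 down adjusted over the list alone; median 1.01). Tnf rose from 233 ± 36.1 to 703 ± 295 CPM (log2 fold change 1.59 ± 0.19, edgeR adjusted p = 2.4e-07), the monocyte attractant Ccl2 by 2.12 ± 0.24 (edgeR adjusted p = 8.32e-08) and the neutrophil attractant Cxcl2 by 2.32 ± 0.20. Cell cycle genes rose in 13 of 15 and fell in 1 (median 1.87). Mcm6, part of the replication helicase, rose by 1.56. RNA of other cells could supply 78.5% of Birc5 (2.99) and 91.9% of Top2a (2.44). Cholesterol synthesis genes rose in 10 of 11 (median 0.63), for example Fdps (0.70 ± 0.12, edgeR adjusted p = 2.95e-05, 51.2% possible from other cells) and Sqle (2.73, 58.6%). Glycolysis genes rose in 7 of 10 and fell in 1 (median 0.63), led by Pgk1 (1.11), Pkm (1.03) and Ldha (0.94). Oxidative phosphorylation genes rose in 9 of 13 (11 adjusted over the list alone; median 0.28). MHC class I genes rose in 8 of 11 and fell in 1 (9 and 1 adjusted over the list alone), with the transactivator Nlrc5 at 1.69 and the peptide transporter Tap1 at 1.12. MHC class II genes rose in 3 of 6, Cd74 by 1.22, H2-DMa by 0.40 and H2-Ab1 by 0.93. The call of H2-Ab1 was lost without day 14 mouse 4.

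Phagocytosis genes passed upward in 7 and downward in 1 of 12 (8 and 1 adjusted over the list alone). The lipid scavenger receptor Cd36 (3.40) and the receptor kinase Axl (2.38) rose and the related Mertk fell (-0.54). Complement genes passed upward in 4 of 6, C4b by 1.80 and C3 by 1.32, without a call of the list (camera adjusted p = 0.0721). Immediate early genes fell in 7 of 16 and rose in 1 (8 and 1 adjusted over the list alone), Zfp36 at -0.85 and Jund at -0.50. All 4 tested naive and memory T cell genes, which include transcription factors that microglia also express, fell: Klf2 at -0.49, S1pr1 at -0.59 and Satb1 at -0.61. Checkpoint genes passed upward in 2 and downward in 2 of 7, where the median was 0.28 and the camera direction downward. Cytotoxic genes passed downward in 1 of 3. Other largest rises were S100a6 (4.46 ± 0.10; 100% possible from other cells), Ifi27l2a (3.07 ± 0.45, edgeR adjusted p = 5.66e-06), Ifi204 (2.44) and Ckap2l (2.36). Largest falls were the histone genes Hist1h2ap (-2.02; 100% possible from other cells at day 14 and 11.9% at day 0), Hist1h1c (-1.56) and Hist1h1e (-1.36), uncertain because near-identical copies can share reads. Others were Gm26669 (-1.42), the neutrophil marker S100a9 (-1.35; 100% possible from other cells at both days) and Rnaset2a (-1.30 ± 0.10, edgeR adjusted p = 3.03e-11). Other counts adjusted over the list alone equalled those over all genes.

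Markers of other cells moved with these groups at day 14. Red cell genes fell in 5 of 5 (median -6.98), Hbb-bs from 765 ± 566 to 6.77 ± 1.22 CPM, and neutrophil genes in 6 of 6 (median -1.72). Lymphocyte markers passed in 0 of 3, with a median of 0.28 and a downward camera direction, and neuron and glia markers in 0 of 6. Lymphocyte markers put RNA of other cells at 2.06% of microglial counts at day 0 and 3.53% at day 14, and neutrophil markers at 1.001% and 2.46%. Markers of the Rhox5 clusters, which held no cells at day 0, put RNA of other cells at 3.06% of microglial counts at day 14 and at 1.90% to 3.66% in the other classes compared. These percents are relative to the level of the markers in the well, so they can rise where the markers fell. Camera called 15 of 20 lists at day 14. The 3 that held with an estimated correlation were cell cycle (adjusted p = 0.0288 with an estimated correlation), cholesterol synthesis (0.0105) and neutrophil markers (0.000531). The camera calls (adjusted p) that were lost were interferon (1.54e-09; adjusted p = 0.200 with an estimated correlation), disease-associated microglia (5.59e-06; 0.166), homeostatic (9.32e-06; 0.200), inflammatory (3.73e-06; 0.162) and red cell (1.62e-05; 0.162). With an estimated correlation the adjusted p was 0.259 for glycolysis, 0.310 for oxidative phosphorylation, MHC class II and phagocytosis. It was 0.357 for MHC class I and immediate early genes and 0.162 for naive and memory T cell genes. In that order the camera adjusted p values were 0.000198, 0.000353, 0.0210, 0.0146, 0.00473, 0.0259 and 0.00928. Aryl hydrocarbon receptor targets had fewer than 3 tested genes in each class and were not tested as a list.

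In total 2510 genes rose and 2018 fell at day 14 among 12560 tested (edgeR, 6 against 6 mice), 515 and 140 of them at least 2-fold, and 755 changed differently from T cells of the same mice. Clusters 2, 1 and 0 held most microglia at day 0 and clusters 7 and 2 at day 14, cluster 7 being led by Gpr84, Tnf, Ccl3 and Il1a. The genes named for day 14 lay beyond all day 0 mice in 6 of 6 mice except C3 and S1pr1 (5), Klf2 (4), C4b (3) and Cd74 and H2-Ab1 (2). Day 14 mouse 4 raised several of them: without it the log2 fold change was 2.81 for Isg15, 5.07 for Spp1, 2.43 for Ifi27l2a, 1.84 for Ifi204 and 0.61 for H2-Ab1. Without day 0 mouse 4 that of C4b was 2.42.

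**Figure D2:**
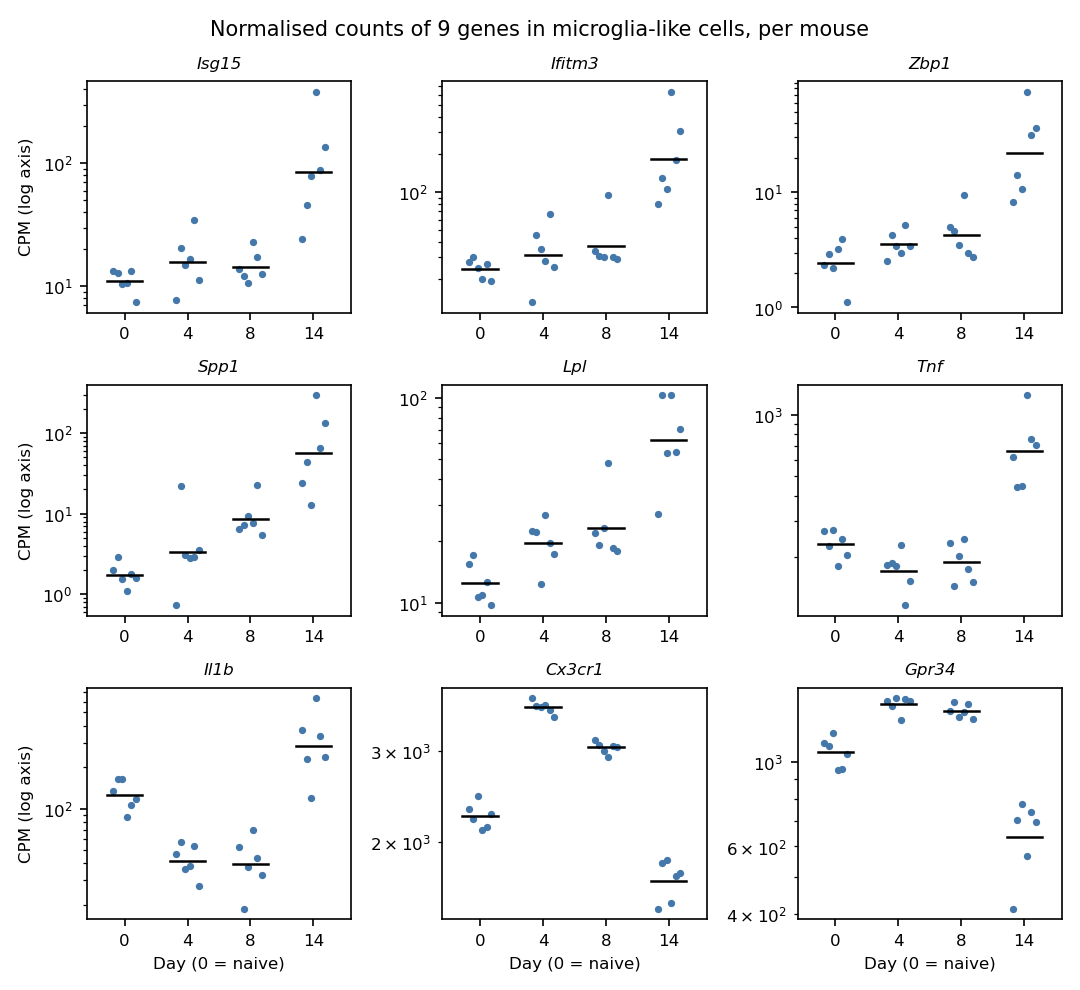
CPM (log axis) of 9 genes in microglia summed per mouse, by day after injection; each dot is 1 mouse, 6 per day, and the line is the geometric mean. Isg15 rose from a mean of 11.3 CPM at day 0 to 126 CPM at day 14, and Il1b fell from 129 to 43.1 CPM at day 4.

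To determine whether surface proteins of microglia changed, antibody counts summed per mouse were compared between day 14 and day 0, relative to the other antibodies of the panel. CD38, an ectoenzyme that consumes NAD, rose most clearly (log2 fold change 1.36 ± 0.09 SE, edgeR adjusted p = 4.5e-12, n = 6 mice a day), from 1.05 ± 0.195 to 20.1 ± 1.32 UMIs per cell. SIRPa, the receptor of the CD47 signal, fell by 1.04 ± 0.07 on the log2 scale (edgeR adjusted p = 4.5e-12), Siglec-H at -0.64 ± 0.05 (edgeR adjusted p = 5.03e-10) and CD11b at -0.58 ± 0.06 (edgeR adjusted p = 5.71e-09). Ly6C changed by 0.50 ± 0.04 (edgeR adjusted p = 9.62e-10), from 55.0 ± 0.610 to 581 ± 7.07 UMIs per microglial cell against 82.5 ± 11.1 and 805 ± 74.6 per T cell. CD38 stood at 22.9 ± 11.7 and 114 ± 24.5 per T cell. The share of antibody background was not estimated, so a change in background is not excluded for these antibodies. CD3, a T cell protein, rose by 1.28 ± 0.13 (edgeR adjusted p = 1.2e-08), from 0.735 ± 0.105 to 13.5 ± 2.69 UMIs per microglial cell against 12.0 ± 3.15 and 123 ± 27.2 per T cell. Of 31 antibodies 12 rose, 9 fell and 10 did not pass. All counts per cell were higher at day 14, when a barcode held a median of 3565 antibody UMIs against 321, so each change is relative to the panel. Without TMM scaling 19 rose and 6 fell, and in limma on centred log-ratios 14 rose and 15 fell, CD11b among the rises (0.08). The 29 calls of limma held 11 of the 21 in the same direction. Relative to T cells of the same mice 4 antibodies changed upward and 12 downward, 8 of them among the 21 in the same direction.

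To extend the day 14 comparison beyond microglia, other classes were compared with day 0, a set of comparisons added after the data were seen. In monocyte-like cells interferon genes rose in 19 of 19 (median 2.96; camera adjusted p = 8.57e-15; adjusted p = 0.106 with an estimated correlation), Isg15 from 35.8 ± 25.04 to 1471 ± 631 CPM (n = 6 mice a day; edgeR adjusted p = 2.69e-08). Inflammatory genes rose in 16 of 17 (median 2.01; camera adjusted p = 1.01e-10; adjusted p = 0.0345 with an estimated correlation), Il1b by 2.01 ± 0.20 (edgeR adjusted p = 1.53e-07) and Ccl5, a T cell attractant, by 5.52 ± 0.69. The T cell attractant Cxcl9 had 0 UMIs at day 0 and 6103 at day 14, at least 360-fold higher over a floor of 3 counts in the group. Timp1 and Upp1 stood at 151 (counting interval 27.1 to 5978) and 179 (31.98 to 7061) times their day 0 sums, in which 1 mouse held the single UMI of each. Counting intervals here and below are binomial, on UMIs pooled over mice, so they leave out the spread between mice. Glycolysis genes rose in 8 of 10 (9 adjusted over the list alone; median 0.75; camera adjusted p = 3.89e-05; adjusted p = 0.211 with an estimated correlation), the glucose transporter Slc2a1 by 1.39. Disease-associated microglia genes rose in 9 of 14 (9 up and 1 down adjusted over the list alone; camera adjusted p = 0.000208; adjusted p = 0.106 with an estimated correlation), Spp1 by 6.35. Largest falls were Ebf1 (-3.48), Igkc (-3.10) and Fabp4 (-2.77), the first 2 genes of B cells and the last among the leading genes of monocyte cluster 34. Lymphocyte markers alone put RNA of other cells at 31.0% of monocyte counts at day 0 and 10.4% at day 14. Igkc (4 of 6 mice beyond all day 0 mice; Fabp4 1) lost its call without day 0 mouse 2 (-2.15) and with Scrublet-called doublets removed (-2.48). Monocyte clusters 5, led by Vcan and Fn1, and 34, led by Treml4 and Ace, held 171 and 92 cells at day 0 and 1444 and 81 at day 14. Of 8944 genes 1704 rose and 1644 fell (edgeR).

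In T cell-like cells interferon genes rose in 18 of 19 (19 adjusted over the list alone; median 2.07; camera adjusted p = 3.87e-17; adjusted p = 0.0520 with an estimated correlation), Usp18 by 2.71 ± 0.40 (edgeR adjusted p = 4.93e-05) and Irf7 by 2.07. Mx1 (3.27) and Ifit3b (3.22) rose too, the last a near copy of Ifit3 and uncertain. The costimulatory receptor Tnfrsf4 rose by 3.10 ± 0.48 (edgeR adjusted p = 7.45e-05). Checkpoint genes passed upward in 4 of 10 (8 adjusted over the list alone; camera adjusted p = 6.85e-05; adjusted p = 0.0520 with an estimated correlation). Immediate early genes fell in 11 of 14 (13 adjusted over the list alone; camera adjusted p = 3.8e-10; adjusted p = 0.0448 with an estimated correlation), Fos at -1.13 and Jun at -1.20. Microglial genes fell in 7 of 10 (P2ry12 -1.51, 89.9% possible from other cells) and neutrophil markers in 4 of 4. The RNA of the whole well that microglial markers would need went from 3.43% to 14.0% of T cell counts. Irf7, Ifit3b and Jun lay beyond all day 0 mice in 5 of 6 mice and P2ry12 in 4. Of 8119 genes 558 rose and 649 fell (edgeR, 6 against 6 mice).

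In NK cell-like cells interferon genes rose in 18 of 18 (median 2.85; camera adjusted p = 1.45e-27; adjusted p = 0.00232 with an estimated correlation), Ifi204 by 4.94 ± 0.59 (edgeR adjusted p = 7.01e-07), Cxcl10 by 4.89 and Isg15 by 3.11. Immediate early genes fell in 8 of 14 (10 adjusted over the list alone; adjusted p = 0.0298 with an estimated correlation), Jun at -0.89, and microglial genes in 5 of 6, Csf1r at -2.18 with 100% possible from other cells. Neutrophil markers fell in 3 of 3 (adjusted p = 0.00165 with an estimated correlation) and complement genes in 3 of 3 (adjusted p = 0.0298 with an estimated correlation), 3 and 3 adjusted over the list alone. The RNA of the whole well that microglial markers would need went from 4.01% to 9.79% of NK counts. The cytotoxic list was not called (2 up, 0 down of 9; 3 and 2 adjusted over the list alone; camera adjusted p = 0.346). Without day 0 mouse 6 the log2 fold change of Ifi204 was 5.58. Clusters 11, led by Gzma and Klra4, and 24, led by Gzmc, held 153 and 166 cells at day 0 and 564 and 107 at day 14. Of 6678 genes 305 rose and 323 fell (edgeR, 5 against 6 mice).

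In neutrophil-like cells inflammatory genes rose in 9 of 11 (11 adjusted over the list alone; median 1.94; camera adjusted p = 2.03e-13; adjusted p = 0.0508 with an estimated correlation), Cxcl2 by 2.21 ± 0.34 (edgeR adjusted p = 0.00125) and Ccl4 by 2.62. Interferon genes rose in 13 of 17 (15 adjusted over the list alone; median 2.32; camera adjusted p = 1.57e-15; adjusted p = 0.0508 with an estimated correlation), Isg15 by 3.47 ± 0.55 (edgeR adjusted p = 0.00125). The granule genes Ngp (-0.75) and Ltf (-0.87) fell. Cluster 17, led by Retnlg and Cxcr2, went from 165 to 308 cells and cluster 18, led by Camp and Ngp, from 308 to 153. Of 5310 genes 231 rose and 93 fell (324; edgeR, 5 against 5 mice). The count was 119 without day 0 mouse 6, 134 without day 14 mouse 3, 162 without day 14 mouse 1, 173 without day 0 mouse 2 and 598 with no low-count filter. Lymphocyte markers alone put RNA of other cells at 27.9% and 35.4% of neutrophil counts at days 0 and 14, and without the genes such RNA could supply 187 passed. Without day 0 mouse 1 the log2 fold change of Isg15 was 4.21.

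In cDC2-like cells, which prime helper T cells, interferon genes rose in 19 of 19 (median 2.36; camera adjusted p = 1.45e-17; adjusted p = 0.0665 with an estimated correlation), Isg15 by 3.64 ± 0.42 (edgeR adjusted p = 1.97e-06). Ifitm1 (4.78) and Serpina3g (4.55) were among the largest rises. Cholesterol synthesis genes rose in 9 of 11 (camera adjusted p = 0.000179; adjusted p = 0.236 with an estimated correlation). MHC class II genes passed downward in 5 and upward in 1 of 7 (camera adjusted p = 0.0179; adjusted p = 0.396 with an estimated correlation). Immediate early genes fell in 14 of 16 (16 adjusted over the list alone; adjusted p = 0.0219 with an estimated correlation), Zfp36 at -1.56. The largest falls were Retnla (-5.70 ± 1.13, edgeR adjusted p = 0.000700), Lpl (-3.60) and Negr1 (-3.26). Microglial genes fell in 10 of 12 (11 adjusted over the list alone; camera adjusted p = 3.24e-06; adjusted p = 0.181 with an estimated correlation). Retnla and Lpl lay beyond all day 0 mice in 5 of 6 mice, and without day 0 mouse 3 their log2 fold changes were -5.06 and -2.78; that of Ifitm1 was 5.65 without day 0 mouse 1. Of 8496 genes 1102 rose and 1386 fell (edgeR, 6 against 6 mice). Lymphocyte markers put RNA of other cells at 7.72% of cDC2 counts at day 0 and 6.84% at day 14.

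**Figure D3:**
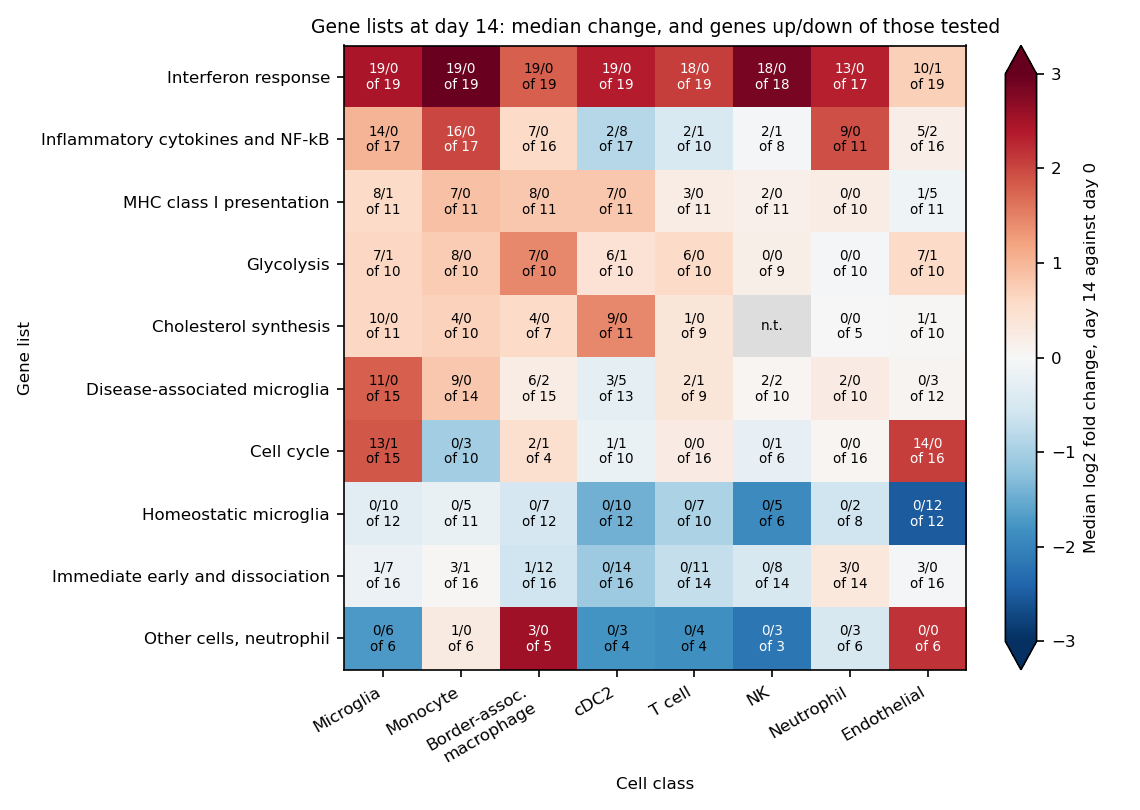
Median log2 fold change of each gene list at day 14 against day 0 (colour) in 8 cell classes (columns), with the numbers of genes that rose and fell of those tested; n.t. marks lists with fewer than 3 tested genes. Interferon response genes have medians of 2.46 in microglia and 2.96 in monocytes, and 0.71 in endothelial cells.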

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

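All tests of explanations here were chosen after the results were seen, as was the change relative to T cells of the same mice; the test for mice that stand apart and the splits of the mice were set by rule.

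Interferon response genes rose in microglia at day 14. If RNA of other cells were the source, 14 other classes, each in the amount its markers reach in microglia, could supply a median of 28.7% of the level of the 19 genes, which argues against it as the whole source, although it reaches over 50% for 4 of them, 75.6% for Irf7, 68.9% for Ifitm3, 66.4% for Cmpk2 and 65.4% for Ifit1. The 12 monocyte markers stood in microglia at a median of 0.487% of their monocyte level and the interferon genes at 12.7%. A factor per gene acting on the whole day 14 well is argued against for 1 gene, Zbp1, which rose more than in T cells of the same mice (difference 1.89, adjusted p = 0.000319). For the other 18, Stat2 with a smaller rise than in T cells among them (difference -1.04, adjusted p = 0.0239), such a factor and a response to metastasis cannot be told apart, because each day was 1 well.

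Hemoglobin genes fell in microglia at day 14, and their median log2 change was negative in all 9 classes, at -6.98 in microglia, -7.83 in T cells, -5.79 in monocytes, -7.89 in NK cells, -6.01 in neutrophils, -7.96 in border-associated macrophages, -9.41 in B cells, -3.88 in cDC2 and -2.39 in endothelial cells. Less RNA of red cells in the day 14 well would lower them in all classes alike. The median of T cells lay -0.841 from that of microglia, but those of cDC2 and endothelial cells lay 3.11 and 4.60 above it, with standard errors of a gene's difference of 1.39 and 1.74, so this explanation stays open. No biological explanation was tested, and perfusion, percoll separation and a change in red cells stay open too.

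Many genes called in microglia moved the same way in T cells of the same mice: 79.6% of those called at day 4, against 59.3% of those not called, and 73.9% at day 14, against 57.9%. A factor per gene for the whole well could give this, and is argued against for the 119 genes at day 4 and 454 genes at day 14 whose change differed from that in T cells in the direction called. For the other genes the well, the shared day 0 mice and an effect of metastasis on both classes cannot be told apart. The 119 and 454 genes are of 12560 tested, while the percents cover 7747 tested in both classes. A difference from T cells also does not exclude RNA of other cells. S100a6 differed by 4.30 at day 14 (edgeR adjusted p = 1.59e-19), although such RNA could supply its full level.

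Changes that differed between microglia and T cells of the same mice numbered 299 at day 4 (187 higher and 112 lower), 229 at day 8 (111 and 118) and 755 at day 14 (485 and 270). In each comparison of days listed below but B cells, only the real split of 100 gave as many calls. The real split is counted, so 1 in 100 is the lowest value that these splits can give. They bear on the number of calls, not on single genes, and were not run for the changes relative to T cells. Real counts and the highest other were 5356 and 1798 for microglia at day 4, 5082 and 1833 at day 8, 4528 and 2362 at day 14, 3348 and 1279 for monocytes, 1207 and 214 for T cells, 628 and 443 for NK cells, 324 and 288 for neutrophils, 2488 and 1084 for cDC2, 1996 and 616 for border-associated macrophages, 3071 and 197 for endothelial cells, and 21 and 19 for antibodies. For B cells the real count was 0, which all 84 of 84 splits reach, so the splits decide nothing there. The highest other split gave 259 calls, and the cause of this number was not tested.

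Antibodies outside the panel had at least 5 UMIs in many barcodes: at day 4 CD335 (97.3%), CD135 (75.6%), CD80 (89.3%), CD223 (52.9%), CD62L (99.1%), CD301b (96.6%), CD127 (98.2%) and CD197 (87.0%), and at day 14 CXCR4 (47.7%) and KLRG1 (63.0%). At day 0 these had 0 UMIs in total except CD62L (304) and CD301b (35). Many barcodes also held them at day 8, for CD335 (91.9%), CD62L (79.6%), CD301b (66.1%), CD80 (64.3%) and CD135 (60.8%), and at day 14 for CD335 (91.3%). CD103, an antibody of the panel, had 19 and 123 UMIs in total at days 4 and 8, against 15044 and 559357 at days 0 and 14. The antibodies that gave counts thus differed between wells.

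In 78 of 611 groups of mice 1 mouse stood apart from the others of its day. Chance would give about 1 in 20 groups if values were normally distributed and groups independent. Some genes here were at 0 in all mice but 1, and the groups reuse the same mice. The number 78 is therefore not shown to exceed chance. The mice that stood apart were day 14 mouse 1 (18 times), day 14 mouse 4 (9), day 0 mouse 6 (8), day 0 mouse 1 (7), day 0 mouse 4 (5), day 0 mouse 2 (4) and others 3 times or fewer. Values below are CPM or percent of cells, with the nearest other mouse in parentheses.

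Day 0 mouse 1 stood apart in neutrophils for Hba-a2 at 473 (81.9), Hbb-bs at 1915 (535) and Hbb-bt at 554 (162), in cDC2 for Hbb-bs at 43.0 (65.0) and Ifitm1 at 172 (61.9), and in NK cells for S100a8 at 179 (72.2) and S100a9 at 339 (141). Day 0 mouse 2 did so for endothelial Fabp4 at 787 (21.7) and in microglia for Itga5 at 113 (79.0), Klf2 at 4252 (3274) and Lag3 at 189 (213). Day 0 mouse 3 had Irf7 at 62.9 (37.9) in NK cells. Day 0 mouse 4 had C4b at 12.2 (3.65) in microglia, Pde1c at 7.77 (2.11) in B cells, Spon1 at 17.6 (3.02) in cDC2, Upp1 at 2.58 (0) in monocytes and 0.324% (0.0530%) of cells in the Spp1 cluster. Day 0 mouse 5 had Gzma at 1.49 (0.984) and Rnaset2a at 57.6 (62.9) in microglia and Timp1 at 2.71 (0) in monocytes. Day 0 mouse 6 had 13.4% B cell-like cells (3.85%), endothelial Apln at 1.22 (0), Cdk1 at 19.5 (3.14) and Ube2c at 18.2 (4.75), microglial C3 at 0.680 (1.47) and Ifi204 at 12.7 (20.5), Cxcl9 at 0.910 (0) in border-associated macrophages and S100a9 at 299.6 (152) in B cells.

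At day 4, mouse 1 had 4.75% B cell-like cells (2.05%), 7.78% cells of the Elane cluster (1.82%) and 20.5% neutrophil-like cells (3.37%), and mouse 2 had 0.505% migratory dendritic cell-like cells (0.165%) and 0.706% cells of the Spp1 cluster (0.247%). Mouse 4 had Klf2 at 1593 (2181) in microglia, and mouse 5 had Alas2 at 3.75 (1.33) and B2m at 2526 (1868) in microglia and 6.74% NK cell-like cells (3.33%). At day 8, in microglia, mouse 2 had Pim1 at 29.2 (48.9), mouse 4 had Birc5 at 6.13 (2.25), Lag3 at 187 (146) and Lpl at 47.8 (23.2), and mouse 5 had H2-Eb1 at 22.2 (8.21), S100a6 at 49.9 (40.4) and Spp1 at 22.4 (9.40).

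Day 14 mouse 1 had 2.28% monocyte-like (11.6%), 2.71% fibroblast-like (1.34%) and 4.45% mural cell-like cells (1.01%). In cDC2 it had Fcrls at 43.4 (25.7), Hbb-bs at 0 (4.14), Lpl at 68.6 (15.2), Negr1 at 47.0 (14.8), Retnla at 115.6 (25.6) and Zfp36 at 871 (541), and in microglia Hbb-bs at 4.43 (6.67), Ngp at 3.88 (5.09), Rnaset2a at 12.7 (24.4) and S100a9 at 68.7 (38.7). It had Lyve1 at 55.0 (11.1) and Zfp36 at 1935 (1245) in border-associated macrophages, Ccl3 at 363 (223) and S100a8 at 59851 (84187) in neutrophils, and Ube2c at 112 (64.3) in endothelial cells. Day 14 mouse 2 had Hba-a2 at 3.08 (1.16) and Zfp36 at 1778 (1600) in microglia and Pgam1 at 309 (210) in border-associated macrophages. Day 14 mouse 3 had endothelial Ackr1 at 1747 (814) and Gpr34 at 22.01 (7.85), and Ifi204 at 38.7 (71.6) in NK cells. Day 14 mouse 4 had in microglia Axl at 125 (49.6), H2-Ab1 at 129.9 (62.1), Ifi204 at 308 (107), Isg15 at 382 (135), Nlrc5 at 77.9 (38.3), Pdcd1 at 38.1 (12.5) and Sqle at 8.08 (4.93), with endothelial Fabp4 at 0 (3.93) and Serpina3g at 131 (54.8) in cDC2. Day 14 mouse 5 had Fos at 352 (238) in T cells.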

How the results depend on the processing

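The alternatives named as added in the processing account, and those for the added classes, were chosen after the data were seen; the others were planned. Of 3172 values of named microglia genes under alternatives 3132 kept direction and side of the threshold and 40 lost their call. Of 2158 in other classes 2127 kept both, 21 lost and 10 gained a call. Of 1689 class shares 1651 stayed on their side of the threshold, 24 lost and 14 gained a call. The named genes were chosen by size of change or p, and 2028 and 1450 of their values leave out 1 mouse. Another 131 and 74 reuse the main p values without genes that RNA of other cells could supply. These stayed on their side of the threshold almost by construction, and the named genes left out there are not counted. Of the 23 list results that camera called in microglia, 4 kept their call with an estimated correlation (2 up and 2 down) and 23 with fry, which called 8 more. Of 90 results of the 6 antibodies with the smallest p, 89 kept their call and 1 reversed: CD11b in limma on centred log-ratios, at 0.0797. The change relative to T cells of the same mice is a different quantity and stands outside these numbers. It passed in the called direction for 2 of 53 named microglia genes at day 4, 8 of 55 at day 8 and 12 of 61 at day 14. The causes were not tested except where fewer genes were tested.

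Relative to T cells the count of called microglia genes went from 5356 to 299 at day 4, 5082 to 229 at day 8 and 4528 to 755 at day 14. Under the other alternatives counts of called genes moved by over 1.5 times in 4 classes. Neutrophils went from 324 to 598 with no low-count filter and to 187 without genes that RNA of other cells could supply, which tests fewer genes (2555 against 5310). Border-associated macrophages went from 1996 to 590 with Scrublet-called doublets removed, and endothelial cells from 3071 to 1775 there and to 1985 without genes that RNA of other cells could supply. B cells went from 0 to 7 with no filter and to 19 in DESeq2.

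With each mouse left out, counts of called microglia genes ranged from 4936 to 5254 at day 4, 4588 to 4925 at day 8 and 3926 to 4615 at day 14. Other ranges were 2886 to 3388 in monocytes, 998 to 1248 in T cells, 489 to 641 in NK cells, 119 to 461 in neutrophils, 2127 to 2590 in cDC2, 1441 to 2041 in border-associated macrophages, 2564 to 2978 in endothelial cells, 0 to 1 in B cells and 20 to 23 antibodies. At day 14 microglia had 2268 rises and 2413 falls with no filter and 2332 and 2269 with cluster 6 added, against 2510 and 2018.

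Share differences (percentage points) that lost their call were T cell-like (3.48), cDC2-like (1.15) at day 14 and endothelial-like (-7.66) at day 4 as a share of cells other than microglia. Those that gained a call there were NK cell-like at day 8 (5.70) and fibroblast-like (-3.13), choroid plexus-like (-0.808) and ILC2-like (-1.05) at day 14.

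No paired analysis was possible because mice of different days are different animals and hashtag numbers carry no pairing. Vehicle mice alone could not be set against vehicle and ABX mice averaged, because treatment is not tied to hashtags and all mice of a day were used together. Not run either were alternatives of the left-out treatment comparisons, limma-voom among them.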

Other observations

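In border-associated macrophage-like cells interferon genes rose in 19 of 19 at day 14 (19 adjusted over the list alone; median 1.78; adjusted p = 0.334 with an estimated correlation), and the resident markers Lyve1, Ccl24 and Cd163 fell (log2 fold change -4.10 ± 0.53, -3.97 ± 0.41 and -3.07 ± 0.37; edgeR adjusted p = 2.39e-05, 4.12e-06 and 1.57e-05, 5 against 6 mice). Cxcl9 stood at 333, with a counting interval of 91.6 to 2758, times its day 0 sum. Pdpn rose by 5.69 ± 0.85 in 4 of 5 mice beyond all day 0 mice. Neutrophil markers rose in 3 of 5 (4 adjusted over the list alone; median 2.54; camera adjusted p = 0.455), and lymphocyte markers put RNA of other cells at 6.89% of counts at day 0 and 18.4% at day 14. Of 8089 genes 1160 rose and 836 fell. Clusters 21 and 26 held 309 and 157 cells at day 0 and 137 and 129 at day 14. Doublets could contribute, since 590 genes passed with Scrublet-called doublets removed. The call of Arg1 (log2 fold change 6.27, edgeR adjusted p = 0.0445) was lost there and without any 1 day 0 mouse or day 14 mouse 4 or 6. In these settings its log2 fold change was 5.62 to 6.74. Without day 14 mouse 6 the log2 fold changes of Ccl24 and Cd163 were -4.68 and -3.91, and without day 14 mouse 1 that of Lyve1 was -4.90.

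In endothelial-like cells Ackr1, a chemokine-binding receptor of venules, rose by 4.84 ± 0.47 and the mitotic genes Cdk1 and Ube2c by 3.58 ± 0.47 and 3.54 ± 0.39 at day 14 (edgeR adjusted p = 2.17e-06, 3.47e-05 and 6.93e-06, 6 against 6 mice). Of the day 14 levels of Cdk1 and Ube2c, 69.8% and 100% could come from RNA of other cells. Apln stood at 491, with a counting interval of 87.9 to 19405, times its day 0 sum. Cell cycle genes rose in 14 of 16 (14 adjusted over the list alone; camera adjusted p = 8.9e-10; adjusted p = 0.401 with an estimated correlation). Interferon genes rose in 10 and fell in 1 of 19 (adjusted p = 0.646 with an estimated correlation). Homeostatic microglia genes fell in 12 of 12 (12 adjusted over the list alone; median -2.50; adjusted p = 0.401 with an estimated correlation). Fabp4 rests on day 0 mouse 2: its log2 fold change of -4.91 was -1.46 without it, and not called, and -0.381 under MULTIseqDemux assignment, also not called. Without day 0 mouse 6 those of Cdk1 and Ube2c were 5.02 and 4.35. Of 10800 genes 1494 rose and 1577 fell. Lymphocyte and neutrophil markers put RNA of other cells at 8.39% and 0.854% of counts at day 0 and 33.8% and 32.2% at day 14, so such RNA could contribute to changes in this class. Microglial markers put it at 12.8% and 17.1%. That percent is relative to the level of the markers in the well, so its rise does not account for the fall of the homeostatic genes. Without the genes that RNA of other cells could supply 1985 passed, and 1775 with Scrublet-called doublets removed. Clusters 15 and 23 held 238 and 229 cells at day 0 and 483 and 138 at day 14.

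In B cell-like cells edgeR called 0 of 6697 genes at day 14 (3 against 6 mice), with 379 at an unadjusted p under 0.05, a lowest adjusted p of 0.117 and 19 calls by DESeq2. Of the 5 genes with the smallest p, none passing, 4 were Pde1c (4.52), S100a9 (-2.12), Tmsb10 (-0.66) and S100a6 (1.77). On simulated data of this size 48 of 50 genes at 4-fold and 17 of 47 at 2-fold were recovered. Interferon genes passed in 0 of 12, and in 7 adjusted over the list alone (camera adjusted p = 8.55e-08; adjusted p = 0.170 with an estimated correlation). Microglial markers put RNA of other cells at 30.6% of B cell counts at day 0 and at 105.5% at day 14, a value too high to be a share. Of the 6697 genes 1252 remained without those that RNA of other cells could supply, 0 of them called. Clusters 20 and 22 held 331 and 313 cells at day 0 and 141 and 65 at day 14.

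The Rhox5 clusters rest on 1 epithelial marker of the fixed lists, Krt8, so no name was given. With Scrublet-called doublets removed their mean share at day 14 was 17.9%, against 17.9% before.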
